A study of Caenorhabditis elegans with 3 samples.

How the data were processed

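Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult hermaphrodites of the nematode Caenorhabditis elegans. Per the labels, the animals came from strain OP383, in which an integrated transgene expresses the product of oef-1 (sequence name F49E8.2) fused at its C terminus to GFP and FLAG tags. They were collected 48 h after synchronization by starvation of first-stage larvae, chromatin was fragmented by sonication, and the fusion protein was precipitated with an antibody against GFP. The label for the antibody names F49E8.2 itself, and the description names GFP; the description was followed. The 3 biological replicates formed 1 group. A second condition, an untagged strain and a strain expressing GFP alone were not analysed here, so no test between groups was made.

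The deposited files were lists of peaks, made by the authors, on the genome builds ce11 and ce10. Per the deposited readme texts, each replicate had its own list of peaks and background regions, called against a control library. A further list was called by the authors on the pooled alignments of the 3 replicates. The final set, called the IDR peaks here (from irreproducible discovery rate), was derived from the 3 replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each peak carried the authors' signal value relative to the control, deposited with no stated scale and therefore used only to rank peaks within a list. Each peak also carried a deposited −log10 q value, which was at the same ceiling for all IDR peaks and was not used to rank. The summit was taken from the offset that the authors deposited for each peak. Read depth is unknown, because the lists give no read counts, and precision is limited by the number of peaks and genes and by the 3 replicates.

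The replicate lists held 30000, 30000 and 26708 peaks and the pooled list 30000, so the lists contain background regions as well as bound sites. For comparisons between replicates, the best peaks of each list by signal were used, as many as there were IDR peaks (1607). The 1607 IDR peaks were the 1607 pooled-list peaks with the highest signal. Replicate values therefore show how far each replicate alone gave the same result, while the IDR set itself combines all 3.

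Coordinates are on ce11, which is WBcel235, and are 1-based. Genes were taken from Ensembl annotation release 115, with 19985 protein-coding genes and 26941 other genes. The start of a gene was the 5′ end of its annotated span, and its promoter window ran from 500 bp upstream to 200 bp downstream. A gene was called bound when an IDR summit lay in this window, so a peak between a divergent pair was assigned to both genes. The ce10 lists served only for counts and chromosome shares. There were 16 gene lists, fixed before the data were examined, and 12 of their names matched no gene. Locations were compared with 1000 random placements of the summits on their own chromosomes, with a two-sided permutation p of which the smallest possible value is 0.001. Gene classes and lists were compared by two-sided Fisher's exact tests with 95% intervals of the odds ratio, and p-values over the 16 lists were adjusted by the Benjamini-Hochberg method. Genes and peaks along a chromosome are not independent replicates, and these p-values measure sampling of genes or peaks and not variation between animals.

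GC content was taken over 100 bp on each side of a summit and compared with the flanks 500 to 700 bp away by 100000 sign permutations over peaks. Sequences of 6 bases, counted together with their reverse complements (2080 in all), were compared between the 50 bp on each side of a summit and an equally long window 500 bp away on the side of lower coordinates. That test was an exact binomial test on discordant peaks with Benjamini-Hochberg adjustment. Peaks around oef-1 and unc-119 were counted in the pooled list and compared with 10000 windows of the same width at random protein-coding genes.

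The genes named were chosen by a rule fixed before the data were examined. It took the gene start nearest to each of the 15 IDR peaks with the highest signal that overlapped one of the 1607 best peaks of every replicate, the 4 members of each list with the highest signal in their promoter window, and oef-1 and unc-119. A gene that the rule selected is not reported here. Alternatives covered the peak set, each replicate alone and left out, the promoter window, the assignment of peaks to genes, the background, the build, the matching of peaks, the sequence windows and the flanking distance. A set without a replicate held the 1607 pooled-list peaks with the best mean rank in the other replicates. The pooled list was still called on all replicates. Such a set therefore changes how peaks were selected and does not fully remove the replicate. The list test was tested on simulated data over the 19985 genes, where 90.5% of lists with an odds ratio of 5 and 1.45% of other lists were called. Genes were drawn independently there, so these rates do not cover peaks shared by several genes or differences between chromosomes. The 6-mer test was tested on 2080 simulated 6-mers, where all 20 planted 6-mers were called and 0 were called with none planted. Simulated summits and flanks had the same base composition, unlike those of the data, so the 0 does not cover calls from composition alone. With the 20 planted, 64 other 6-mers were called too, overlapping ones included, and 17 of the 20 smallest p belonged to planted ones, so a count of called 6-mers is not a count of separate motifs. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.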

Results

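Binding of OEF-1, a protein of the germ line, was mapped by ChIP-seq in young adult C. elegans hermaphrodites, whose gonads hold germ cells in meiosis and growing oocytes. The series held 3 biological replicates of 1 transgenic strain, collected 48 h after synchronization, and addressed where the tagged protein sits in the genome. The authors' final set held 1607 IDR peaks on ce11 and 1497 on ce10. Their median width was 340 bp, and the authors' signal ran from 32.2 to 1147 with a median of 46.5. Promoter windows of 1032 of the 19985 protein-coding genes (5.16%) contained an IDR summit. These include 10 of the 12 protein-coding genes of the mitochondrial genome.

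Of the 25 strongest nuclear peaks found in every replicate, a number chosen after seeing the data, 18 had the summit in the promoter window of the nearest gene. The other 7 lay further away, from −7748 to 4277 bp relative to the start. The highest nuclear signal, 366, was at rpl-3 (WBGene00004414), a gene for a protein of the large ribosomal subunit. That peak spanned chromosome III from 3867427 to 3867718, in intergenic sequence, with its summit at −270 bp relative to the gene start, and it ranked 13, 10 and 6 in replicates 1, 2 and 3. Peaks at rpl-35 on III (signal 266) and at cdc-48.1 on II (signal 253), which encodes an AAA ATPase of protein degradation, followed. The peak upstream of zen-4 (IV, 6117775 to 6118087, signal 208), a kinesin of cytokinesis, lay in intergenic sequence. At kel-3 (III, signal 193), the summit fell in a 3′ UTR at −220 bp relative to the start. Next came rpl-15 (IV, 189), the histone gene his-68 (I, 187), drr-2 (III, 186), the eggshell proteoglycan gene cpg-1 (III, 184) and Y17G9B.5 (IV, 182), which shares its peak with rpl-20. The other 5 of the 15 strongest replicated peaks lay on the mitochondrial genome, with signals from 396 to 1147. They were nearest to the start of COX3 and of 4 mitochondrial genes that carry no symbol in the annotation used (WBGene00010967, WBGene00000829, WBGene00010964 and WBGene00010965). The mitochondrial genome carried 23 IDR peaks in all, and whether they reflect binding of OEF-1 was not tested.

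Each replicate placed most IDR peaks among its best, but only a minority were among the best of all 3. On average 66.5% ± 2.83 (SD, n = 3) of IDR peaks had their summit in one of the 1607 best peaks of a replicate, with 69.3% in replicate 1, 66.6% in replicate 2 and 63.7% in replicate 3. Counting each complete list, which also holds background regions, 97.1%, 94.8% and 93.7% of the IDR peaks were found. All 3 replicates placed 567 of the 1607 IDR peaks among their best, and 62 were among the best of none. Pairs of replicates shared 48.4% ± 0.701 (SD, n = 3 pairs) of their 1607 best peaks. Across IDR peaks matched in a pair, which are not independent replicates, Spearman's rho of the signal was 0.365, 0.367 and 0.399.

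OEF-1 peaks concentrated immediately upstream of protein-coding genes. Of the 1607 summits, 813 (50.6%) lay in a promoter window, against 13.7% ± 0.860 (SD over 1000 random placements), which was 3.68 times as many (permutation p = 0.001, the smallest possible). The best peaks of the replicates gave 47.2% ± 3.09 (SD, n = 3). Of the 67.8% of summits within 1000 bp of the nearest start, 75.4% were upstream. The 100 bp bin with the most summits, from 200 to 100 bp upstream, held 202 summits against 32.3 in random placements. Coding exons held 8.59% of summits against 25.9% in placements, and introns 17.4% against 33.9%. Summits were more frequent than in placements in 5′ UTRs (2.86% against 1.39%), in 3′ UTRs (8.34% against 3.48%) and in intergenic sequence (62.9% against 35.3%). Each of these 5 differences had the smallest possible permutation p, 0.001. Pooled-list peaks outside the IDR set lay in promoter windows in 17.7% of cases (odds ratio of IDR peaks against these 4.75, 95% interval 4.28 to 5.27, Fisher's exact p = 5.92e-183).

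**Figure D1:**
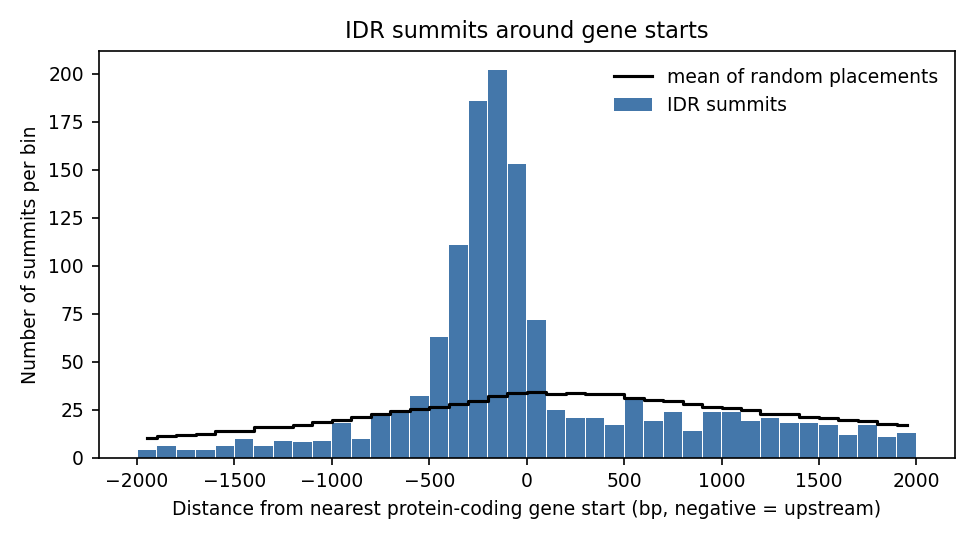
Number of IDR summits (bars, 100 bp bins) by distance in bp from the nearest protein-coding gene start, with negative values upstream, and the mean of random placements (line). The bin from 200 to 100 bp upstream reaches 202 summits against 32.3 in placements.

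Strong peaks lay at promoters more often than weak ones. The promoter share was 54.5% of 536 peaks in the upper tertile of signal, 51.3% in the middle and 46% in the lowest. Top and bottom tertiles differed with an odds ratio of 1.41 (95% interval 1.1 to 1.8, Fisher's exact p = 0.00596).

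Genes of meiosis and of oocytes were among those bound most often. Of 56 genes of oogenesis and maternal RNA regulation, 25 (44.6%) were bound, against 5.05% of other genes (odds ratio 15.2, 95% interval 8.54 to 26.6, adjusted p = 3.22e-17, Fisher's exact test). They were led by cpg-1 and cpg-2 (ranks 26 and 72 among the IDR peaks), which encode eggshell proteoglycans, by mex-5 (rank 77), an RNA-binding protein of zygotic polarity, and by egg-1 (rank 127), which acts in fertilization. Of 50 meiosis genes, 19 (38%) were bound (odds ratio 11.4, 95% interval 6.09 to 21, adjusted p = 7.92e-12, Fisher's exact test). The strongest were rec-8 and coh-3 (ranks 77 and 98), kleisin subunits of meiotic cohesin, and syp-4 and syp-5 (ranks 117 and 132), which encode proteins of the synaptonemal complex. The genes rec-8 and mex-5 are divergent neighbours and share 1 peak on IV from 13353252 to 13353516. In the replicates taken singly, 35.1% ± 7.43 of oogenesis genes and 29.3% ± 6.43 of meiosis genes were bound (SD, n = 3).

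Germ granule and small RNA genes were bound at 8 of 46 (17.4%, odds ratio 3.89, 95% interval 1.56 to 8.49, adjusted p = 0.00397, Fisher's exact test). The members with the highest signal were hrde-1 (105) and wago-4 (80.4), which encode Argonautes, mut-15 (70.0), and the helicase gene znfx-1 (62.6). The wago-4 peak ranked 48 in replicate 1 but 2084 and 2950 in the others. In replicates 1, 2 and 3 alone the odds ratio was 3.99, 3.67 and 3.26. It was 5.60, 6.16 and 6.95 without replicate 1, 2 and 3, in sets that re-rank the pooled list and so also change the selection of peaks. With a promoter window of 250 bp upstream to 100 bp downstream it was 2.95, and the list no longer passed (adjusted p = 0.0812, Fisher's exact test). The list of 77 spermatogenesis genes, of which 1 was bound, did not pass the test against other genes (odds ratio 0.241, 95% interval 0.00602 to 1.39, adjusted p = 0.189, Fisher's exact test; odds ratio 0.517 without replicate 2).

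Genes for growth and division, used in many tissues, were bound as well. Of 79 cytoplasmic ribosomal protein genes, 55 were bound (69.6%, the highest share of the 16 lists, odds ratio 44.4, 95% interval 26.9 to 75.3, adjusted p = 2.26e-51, Fisher's exact test). Signals at rpl-3, rpl-35, rpl-15 and rpl-20 were 366, 266, 189 and 182, and single replicates gave 59.1% ± 5.27 (SD, n = 3). That rank depended on the promoter window. From 250 bp upstream to 100 bp downstream, the odds ratio was 6.77, below oogenesis (12.6), meiosis (11.0), proteasome (8.38) and splicing genes (7.27). Of 53 splicing genes, 17 were bound (odds ratio 8.80, 95% interval 4.62 to 16.1, adjusted p = 2.06e-09, Fisher's exact test), among them the SR protein gene rsp-6 (73.5), cdc-5L (62.1) and the Sm protein genes snr-1 (53.3) and snr-3 (48.2). The snr-3 peak is shared with rsp-5, another member of the list, and rsp-1 and rsp-2, outside the rule for named genes, also share a peak. Some ribosomal protein genes share a peak too, such as rps-10 and rpl-24.1. In both lists the count of bound genes therefore exceeds the count of peaks. Of 68 genes of cell cycle and chromosome segregation, 19 were bound (odds ratio 7.24, 95% interval 4.01 to 12.6, adjusted p = 2.40e-09, Fisher's exact test), and the odds ratio was 4.78 without replicate 1. They included mcm-2 (123) of the replicative helicase, the topoisomerase gene top-2 (93.5), pcn-1 (69.4) and zyg-1 (69.1), a kinase of centriole duplication.

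Among 33 proteasome genes 8 were bound (odds ratio 5.92, 95% interval 2.30 to 13.6, adjusted p = 4.30e-04, Fisher's exact test), led by rpn-3 (94.3), rpn-9 (55.2), pbs-1 (52.9) and pas-4 (46.5). The pas-4 summit lay in no peak of replicate 3. Restricted to the 567 peaks among the best of every replicate, neither the proteasome list (odds ratio 1.5, adjusted p = 0.659, Fisher's exact test) nor the splicing list (2.89, adjusted p = 0.167, Fisher's exact test) passed. The proteasome list also missed the threshold with the higher-signal peaks (3.44, adjusted p = 0.106, Fisher's exact test) and without divergent genes (5.83, adjusted p = 0.0935). Chromatin regulators were bound at 10 of 43 (odds ratio 5.61, 95% interval 2.46 to 11.7, adjusted p = 1.19e-04, Fisher's exact test). Their strongest members were lin-54 (96.9), oef-1 itself (96.4), the chromodomain gene mrg-1 (85) and lin-53 (84.8). The lin-54 peak is shared with the ribosomal protein gene rpl-12. Without peaks within 50 kb of oef-1 the odds ratio of chromatin regulators was 4.91 (adjusted p = 5.68e-04, Fisher's exact test). Mitochondrial ribosomal protein genes, bound at 6 of 69, did not differ from other genes (odds ratio 1.75, 95% interval 0.619 to 4.05, adjusted p = 0.188, Fisher's exact test), although they passed in replicate 1 alone (odds ratio 2.84, adjusted p = 0.0121). The strongest signals there were 55.7 at mrps-7, 46.6 at mrpl-32, 43.4 at mrps-15 and 42.9 at mrpl-36.

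Core histone genes were bound at 8 of 72 (odds ratio 2.31, 95% interval 0.952 to 4.84, adjusted p = 0.0462, Fisher's exact test). These 8 formed 4 divergent pairs, each sharing 1 peak, such as his-67 and his-68 (signal 187) and his-59 and his-60 (93.5). With divergent genes left out, 0 remained bound (odds ratio 0). The list passed in 10 of 18 alternatives. It missed the threshold without replicate 1 (odds ratio 1.82, adjusted p = 0.18, Fisher's exact test), without replicate 2 (1.77, adjusted p = 0.184), and in replicates 2 and 3 alone (2.2 and 1.97). The same held when any overlap counted (2.08), with gene bodies included (1.89) and with autosomal genes only (2.14).

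Tissue-specific somatic genes were rarely bound. Of 1308 chemoreceptor genes 5 were bound (odds ratio 0.0659, 95% interval 0.0213 to 0.155, adjusted p = 2.65e-23, Fisher's exact test), namely sri-5 (59.9), srw-95 (50.6), srbc-58 (42.7), srh-269 (38.3) and, outside the rule for named genes, srh-16 (36.5). Of 173 cuticle collagen genes, col-38 (55.9) and col-2 (40.5) were bound (odds ratio 0.213, 95% interval 0.0256 to 0.784, adjusted p = 0.0148, Fisher's exact test). Both col summits lay at −437 bp relative to the start in peaks shared with a divergent gene, rpl-5 and ndc-80 respectively. The collagen call was lost with the higher-signal peaks only (odds ratio 0.198, adjusted p = 0.145, Fisher's exact test), with peaks in every replicate (0.277, adjusted p = 0.436) and with the window of 1000 bp upstream to 500 bp downstream (0.426, adjusted p = 0.0717). It held without replicate 1 (0.115, adjusted p = 0.00573, Fisher's exact test) and without replicate 2 (0.112, adjusted p = 0.00598). No bound gene was found among 67 neuronal, 55 intestinal and 47 muscle genes. With so few members these lists did not pass either (adjusted p = 0.0668, 0.144 and 0.188, Fisher's exact test), and upper bounds of their odds ratios were 1.04, 1.27 and 1.5. The neuronal list passed with the wider window (adjusted p = 0.0318, Fisher's exact test) and when any overlap of peak and window counted (adjusted p = 0.0478).

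**Figure D2:**
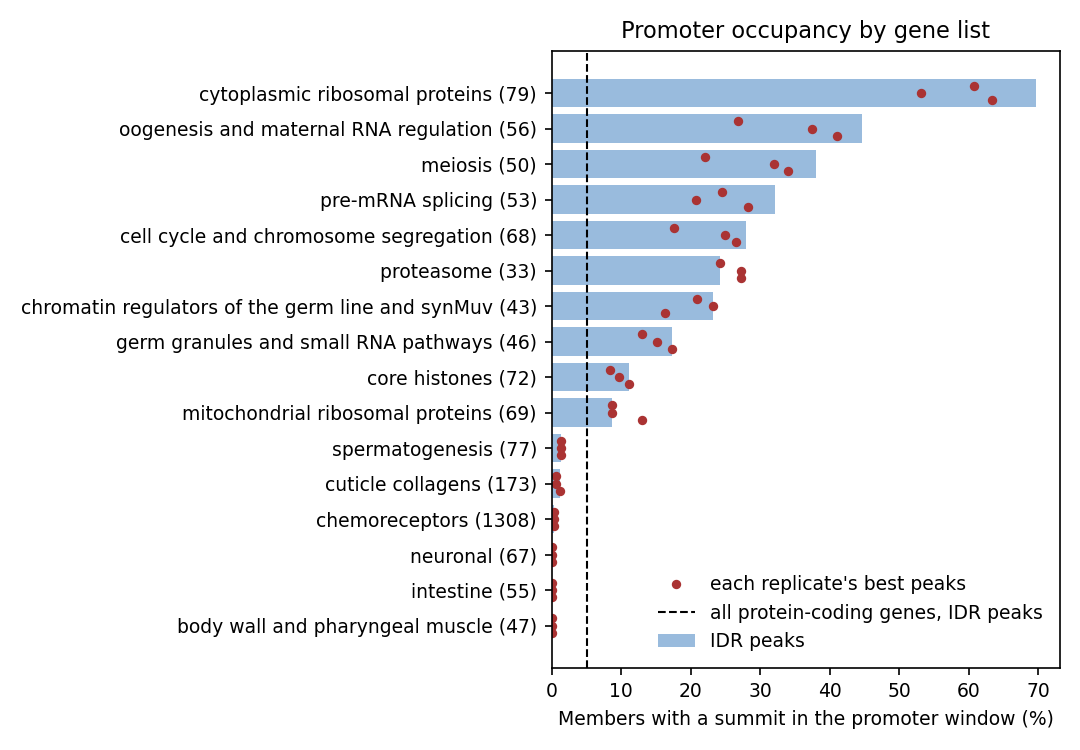
Percent of the members of each gene list (number of members in parentheses) with a summit in the promoter window, for the IDR peaks (bars) and for the 1607 best peaks of each replicate (points). Ribosomal protein genes reach 69.6%, and the dashed line marks the 5.16% of all protein-coding genes.

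The X chromosome carried few OEF-1 peaks. It held 60 IDR peaks, or 3.39 per Mb (95% Poisson interval 2.58 to 4.36), against 18.5 per Mb on the autosomes (17.5 to 19.4). Of 2731 X-linked genes 5 were bound (0.183%), against 1017 of 17242 autosomal genes (5.90%, odds ratio 0.0293, 95% interval 0.00947 to 0.0686, Fisher's exact p = 1.48e-58). The 5, named after their values were seen, were sor-3, smvt-1, stn-2, latd-1 and M163.11, and each of their summits lay within 200 bp of a tRNA, snoRNA or snRNA gene. Among the autosomes, chromosome V had 10.8 peaks per Mb and the others 18.4 to 22.2. The X share was 0.187% in the upper tertile of signal, 3.54% in the middle and 7.48% in the lowest. In the best peaks of each replicate the X share was 2.61% ± 0.0622 (SD, n = 3), below the 3.73% of the IDR set.

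**Figure D3:**
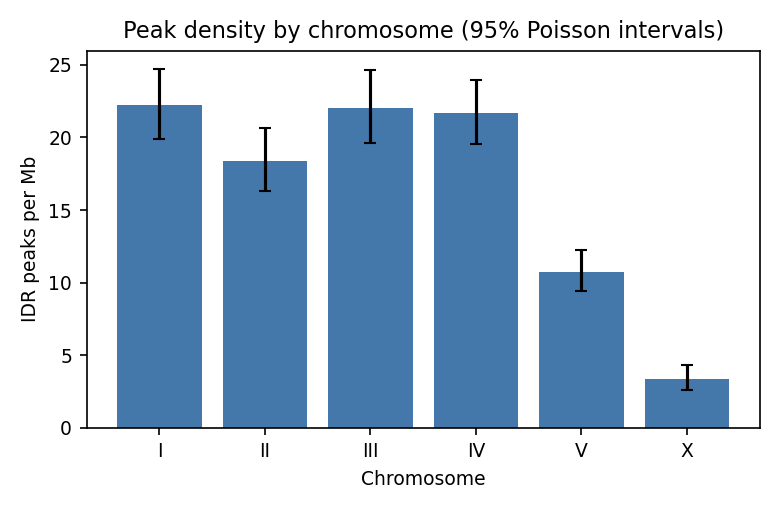
IDR peaks per Mb for each nuclear chromosome, with 95% Poisson intervals as error bars, which cover counting error only. The X has 3.39 peaks per Mb and the autosomes between 10.8 and 22.2.

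Peak positions followed gene arrangement. Genes with a divergent neighbour starting within 1000 bp were bound in 13.7% of 3539 cases, against 3.33% of 16446 others (odds ratio 4.62, 95% interval 4.05 to 5.26, Fisher's exact p = 1.22e-110). Each peak between such a pair counts for both genes. Genes starting within 500 bp downstream of a gene on the same strand, an arrangement that includes operons, were bound in 7.40% of 3621 cases, against 4.67% of others (odds ratio 1.63, 95% interval 1.41 to 1.89, Fisher's exact p = 1.35e-10). With divergent genes left out, in a comparison chosen after seeing the data, that odds ratio was 3.62. On the autosomes, 61.4% of summits lay in the central part of the chromosome, defined as its middle 50%, against 55.7% of gene starts (odds ratio 1.27, 95% interval 1.14 to 1.41, Fisher's exact p = 1.43e-05).

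Sequences with the dinucleotide CpG led the 6-mers enriched at summits, though GAGACC, among the leading 6, holds none. Such 6-mers were not tested as a class. GC content was 39.6% over 100 bp on each side of the summit and 38.5% in the flanks, a mean difference of 1.1 percentage points (SD 8.82 over 1605 peaks, permutation p = 1e-05, the smallest possible). It was 4.42 points higher over 50 bp on each side, and 1.81 points lower than the flanks over 250 bp, so that the sign depends on the window. Taken per gene over 1022 bound nuclear genes, promoter summits had 39.6% GC against 34.7% at the same offsets of unbound genes (permutation p = 1e-05). A summit shared by several genes was counted for each, so these values are not independent. Of 2080 6-mers, 325 were more frequent at summits than in the flank and 275 less frequent. The smallest p belonged to GGCGCA, or TGCGCC on the other strand, found at 12.8% of summits and in 2.36% and 2.74% of the lower and higher flanks (adjusted p = 6.82e-28, exact binomial test). ACGCGC (9.77% of summits against 1.06%), GAGACC (14.4% against 3.30%) and ACCGTA (12.6% against 2.61%) were also among the leading 6. CTGAAA was depleted, at 10.7% of summits against 23.3%. The 6-mers were compared with flanks only and not with unbound promoters. Their enrichment and depletion therefore cannot be told apart from general differences between promoters and other sequence.

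The transgene adds the oef-1 region to the genome, and unc-119 is the usual rescue marker of such strains, so peaks near both were counted. An IDR peak with signal 96.4 spanned IV from 7548379 to 7548500, with its summit in the 5′ UTR of oef-1, 2 bp inside the start. It ranked 196, 165 and 134 in the replicates. Within 20 kb of oef-1 (IV, 7548417 to 7551519) the pooled list held 32 peaks, more than in 96.4% of random gene windows, whose median was 12 and whose upper limit of the central 95% was 33. The replicate lists held 32, 34 and 32 peaks there, more than in 98.4%, 99.3% and 99.2% of windows, and 4 IDR peaks lay there. Within 50 kb the count of 53 exceeded 87.4% of random windows. Around unc-119 on III, the pooled list held 20 peaks within 20 kb, more than in 71.3% of random windows, and no IDR peak.

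**Figure D4:**
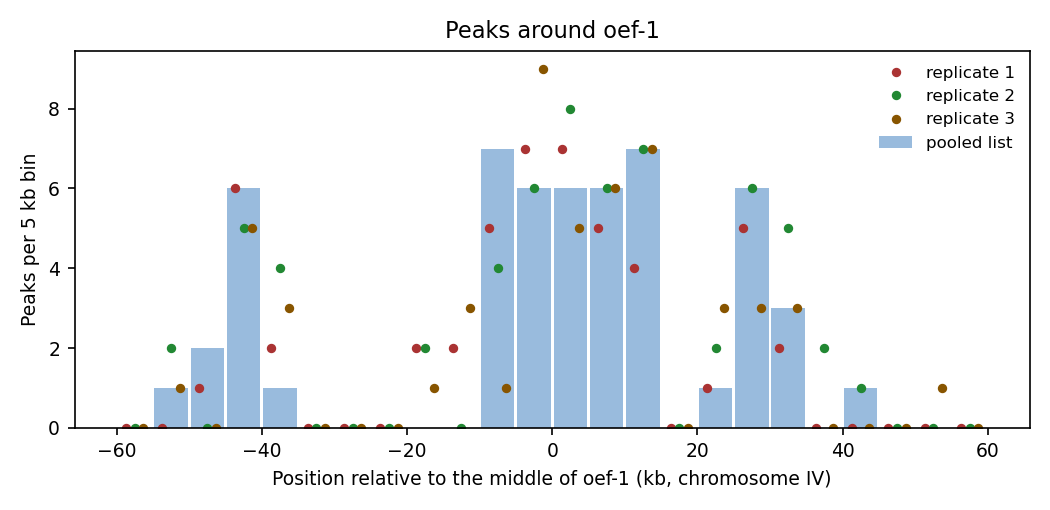
Peaks per 5 kb bin around the middle of oef-1 on chromosome IV (kb), in the pooled list (bars) and in each replicate list (points, shifted sideways for visibility). The 5 bins from 10 kb before to 15 kb after the middle hold 6 or 7 pooled-list peaks each.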

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

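The tests of X-linked tRNA genes, of X-linked members within lists, of abundant somatic genes and of extra copies around oef-1 were chosen after the results they concern were seen (the 10 kb width was planned), and small RNA genes were examined only after peaks had been noticed there. Other tests in this part were specified before their values were known, but after the patterns had been seen. Signals fell outside the genes and regions that the main comparisons used in 3 places: the mitochondrial genome with 23 IDR peaks, tRNA genes with 169 IDR summits within 200 bp, and the surroundings of oef-1 with 28 pooled-list peaks that were not in the IDR set.

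The mitochondrial genome held 26, 24 and 13 of the 1607 best peaks of replicates 1, 2 and 3. Its IDR peaks had a density of 1667 per Mb (95% Poisson interval 1057 to 2502), against 18.5 per Mb on the autosomes. Whether these peaks reflect binding of the fusion protein or another source of signal was not tested.

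Few protein-coding genes were bound on the X. A general loss of signal on that chromosome is argued against by its tRNA genes, of which 63 of 276 had a summit within 200 bp, against 129 of 336 on the autosomes (odds ratio 0.475, 95% interval 0.326 to 0.688, Fisher's exact p = 3.74e-05), although a ratio below 1 leaves a partial loss open. A lack of suitable genes on the X is argued against as the whole cause by the 4 lists above the other genes that had X-linked members, in which 0 of 14 were bound where 3.4 were expected from the same lists (odds ratio 0, upper bound 0.717, exact p = 0.0120, stratified by list). It stays open as a part, since only 2.80% of the 500 members of the 9 lists were X-linked, against 13.7% of all genes. The 9 lists were picked with the same IDR peaks. The 14 X-linked members include 4 of the histone list and related meg genes, so they are few and not independent. Low transcription of the X in germ cells may account for the pattern, and no biological explanation was tested, because the design has 1 group.

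Many peaks lay at ribosomal protein genes and at tRNA, snoRNA and snRNA genes, a pattern that could arise where highly transcribed chromatin collects signal without specific binding. Neighbouring small RNA genes do not carry the ribosomal protein result, since without peaks near them the odds ratio was 44.3 (95% interval 26.9 to 74.5). If any highly transcribed gene of the animal collected signal, abundant somatic genes would be bound, and 0 of 31 were (odds ratio 0 against ribosomal protein genes, upper bound 0.0628). However, 28 of the 31 belong to lists whose values were already known when the set was chosen. The outcome for those genes was therefore known in advance and does not test that explanation. The other 3, taken alone, were too few to decide (odds ratio 0 against ribosomal protein genes, upper bound 1.15). High transcription in germ cells cannot be told apart from specific binding at the 69.6% of ribosomal protein genes that were bound. Whether high transcription elsewhere in the animal collects signal was not decided either, although 0 of the 31 genes were bound. No expression values and no ChIP of another protein were used here.

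Weak peaks were dense around oef-1, where within 10 kb the pooled list held 30 peaks, more than in 99.9% of random windows, as did each replicate list (27, 28 and 27 peaks, all above 99.9% of windows). Extra copies of the region in the transgene are a candidate explanation that stays open, since a count of the same peaks cannot favour it over other causes. Broad occupancy of genes expressed in the germ line is argued against as the whole cause, since 1 of 152 windows at germ-line list genes (0.658%) held as many. These windows had a median of 13 peaks against 6 at random genes, so a contribution of that kind stays open. No biological explanation was tested by the design.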

How the results depend on the processing

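The alternatives without mitochondrial peaks, without peaks within 50 kb of oef-1, without peaks near tRNA, snoRNA and snRNA genes, and with gene families of at least 8 members were chosen after seeing the data. Promoter share, the contrast of X with autosomes, tandem and divergent genes and chromosome position kept their direction and call under all alternatives run. The promoter share ranged from 33.7% to 61.7% and the odds ratio of the X from 0 to 0.107. Taking the best peaks of the pooled list moved nothing, since these are the IDR peaks themselves. The X share of peaks was 2.61%, 2.55% and 2.68% in replicates 1, 2 and 3 alone and 0.388% without peaks near small RNA genes, which were 55 of the 60 X peaks. Lists above the other genes, 9 in all, ran from 7 (peaks among the best of every replicate, or divergent genes left out) to 10 (replicate 1 alone), and their members changed. Lists below the other genes fell from 2 to 1 with the higher-signal peaks and with peaks among the best of every replicate, 2 smaller sets, and rose to 3 when any overlap of peak and window counted. Requiring 50% reciprocal overlap put 59.6% of IDR peaks among a replicate's best. Peaks shared by replicate pairs were 46.5% with that overlap, 53.0% with 1 bp, 50.5% with 50% as many peaks and 40.9% with 2 times as many. For these the cause was not tested. Leaving a replicate out leaves a single pair. The resulting values, between 47.9% and 49.2%, are those of the main comparison and are no further test. The pooled-list count around oef-1 at 20 kb lay within the central 95% of random windows (one-sided permutation share 0.0357). It lay above at 10 kb (99.9% of windows held fewer) and at 20 kb in replicates 1, 2 and 3 alone (98.4%, 99.3% and 99.2%), and again within at 50 kb (87.4%), where more distant sequence is included. GC content turned to 1.81 points below the flanks (−1.81) at 250 bp. The higher-signal peaks gave 202 enriched 6-mers in place of 325, with fewer peaks tested. Mitochondrial ribosomal protein genes went to an odds ratio of 0 with peaks in every replicate, histones to 0 without divergent genes, and neuronal genes to 1.06 with gene bodies included, none past the threshold; the cause was not tested. Read depth is unknown, so a missing peak does not show absence of binding.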

Other observations

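The analyses in this part were chosen after seeing the data. The tRNA, snoRNA and snRNA genes of the nucleus carried many OEF-1 peaks. Of 1584 nuclear summits, 169 lay within 200 bp of a tRNA gene, 93 of a snoRNA gene and 57 of a snRNA gene, against 3.39, 3.30 and 1.15 in random placements (permutation p = 0.001 for each, the smallest possible). Thus 192 of 612 tRNA genes (31.4%), 92 of 346 snoRNA genes (26.6%) and 49 of 129 snRNA genes (38%) had a summit. In the best peaks of single replicates, tRNA genes took 8.17% ± 1.28, snoRNA genes 5.08% ± 0.558 and snRNA genes 3.11% ± 0.494 of the peaks (SD, n = 3). These replicate shares include mitochondrial peaks and genes, so they are not directly comparable with the counts of nuclear summits. The genes of piRNAs, short germ-line RNAs that pair with Argonautes, had 25 summits against 69.7 in placements (permutation p = 0.001). At miRNA genes there were 6 summits against 1.83 in placements (permutation p = 0.00999), and 6 of 261 genes (2.30%) had a summit. Genes annotated as ncRNA had 260 summits against 47.1, and pseudogenes 27 against 60.5 (permutation p = 0.001 for each). Counts at lincRNA genes (5 against 4.94) and rRNA genes (0 against 0.308) were close to placements. None of these p-values was adjusted for the number of gene kinds compared. Together tRNA, snoRNA and snRNA genes accounted for 318 nuclear peaks, of which 270 lay outside promoter windows of protein-coding genes. On the X, 55 of 60 peaks (91.7%) lay near such genes, against 17.3% of autosomal peaks (odds ratio 52.7, 95% interval 20.9 to 169.9, Fisher's exact p = 1.73e-34).

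Among 138 gene families outside the lists, defined by name and with at least 10 members, 2 were bound more often and 2 less often than other genes. Subunits of RNA polymerase (rpb) were bound at 5 of 11 genes (rpb-12, rpb-11, rpb-3, rpb-9 and rpb-10; odds ratio 15.4, adjusted p = 0.00595, Fisher's exact test). DnaJ-domain chaperones (dnj) were bound at 8 of 29 (odds ratio 7.04, adjusted p = 0.00551, Fisher's exact test). Of 269 nuclear hormone receptor genes (nhr) only nhr-47 was bound (odds ratio 0.0676, adjusted p = 0.00263, Fisher's exact test), and of 238 C-type lectin genes (clec) only clec-88 and clec-57 were (odds ratio 0.154, adjusted p = 0.0196, Fisher's exact test). The count depended on the minimum size: with at least 8 members, 3 of 196 families were bound more often and 2 less often. The added family was the chaperonin subunits (cct), bound at 5 of 8 (odds ratio 30.8, adjusted p = 0.00187, Fisher's exact test).

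Pooled-list summits were also counted inside genes, beyond 500 bp from the start, where 9 of the 16 lists exceeded random gene lists and 3 fell below them. Ribosomal protein genes had 1.11 summits per kb, proteasome genes 1.05, germ granule genes 0.811, oogenesis genes 0.785 and cell cycle genes 0.627 (adjusted permutation p = 2.67e-04 for each). Chromatin regulators had 0.603, meiosis genes 0.591, splicing genes 0.534 and mitochondrial ribosomal protein genes 0.479 (adjusted permutation p = 4.00e-04, 4.00e-04, 0.00249 and 0.0212). The ribosomal value rests on the 17 genes of that list long enough to be counted, with 14 summits in 12.6 kb. Random gene lists gave 0.311 to 0.314 on average for these 9. Neuronal genes had 0.194 summits per kb, muscle genes 0.113 and chemoreceptor genes 0.105 (adjusted permutation p = 0.0445, 0.00464 and 2.67e-04). Spermatogenesis genes had 0.379 (adjusted permutation p = 0.451).

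Genes in tandem were bound more often both when the upstream gene ended within 200 bp (6.67%, odds ratio 1.46, Fisher's exact p = 2.47e-04) and between 200 and 500 bp (8.21%, odds ratio 1.83, Fisher's exact p = 2.30e-09), against 4.67% of genes without such a neighbour. With divergent genes left out, the odds ratio of tandem genes was 3.62 (95% interval 3.04 to 4.32, Fisher's exact p = 7.52e-46). Away from tRNA, snoRNA and snRNA genes, the 6-mer with the smallest p was ACCGTA, at 15.9% of summits against 2.05% in the flank (adjusted p = 1.85e-33, exact binomial test).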
